A study of Homo sapiens with 32 samples.

How the data were processed

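RNA was extracted from human quadriceps biopsies with TRIzol and a column kit, per the labels' protocols. Reads were aligned with STAR 2.7.8a to hg19 and handled in Partek, and DESeq2 is named without a role, per the submitters' processing notes. The feature filter applied before deposit, the annotation and the strand setting are not given in the sources used here, so genes that overlap or share sequence cannot be separated with certainty. The deposited table holds estimated counts per gene for 32 libraries, not normalized, and 72.0% of its values are whole and 76.9% lie within 0.001 of a whole number. Fractional values arise where reads are shared between genes or transcripts, which makes the values of near-identical genes uncertain. The table has 18807 rows, of which 6 are 0 in every library and 23 carry a damaged, repeated or joined symbol; these 23 stayed in the fit and are not named. Gene coordinates are those of the deposited table, given as 1-based inclusive positions.

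Expected counts as deposited were rounded to whole numbers. Genes were kept by edgeR's filterByExpr, libraries were scaled by TMM, and the limbs were compared with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3, with the sample code as a block and Benjamini-Hochberg adjustment at 0.05. Standard errors were derived from the fold change and its F statistic. DESeq2 1.42.0 and limma 3.58.1 (voom) were alternatives. The block follows from the sample titles, in which each code occurs once per limb; the labels do not say outright that a code is a person, and the block was used in the main model for that reading of the titles, with the unblocked model as an alternative. The deviations of same-code libraries from their limb mean correlated with a median r of 0.44 across genes, against -0.03 for other pairs, and exceeded 0.1 in 12 of 16 pairs. Of the 16 libraries of each limb, 8 correlated best, among those of the other limb, with that of their own code. The limbs matched in sex-linked expression in 16 of 16 pairs, but how often libraries of different codes matched is not given here. Because not every pair passed 0.1, the data alone do not establish the pairing.

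A total of 30 pathway lists and 13 cell type marker lists, the rule for naming genes, the main tests and most alternatives were fixed before the data were examined. Of 1156 list entries 1133 were matched, 25 of them through older symbols, and 23 were not analysed. Lists were tested with camera on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over each family. Camera with an estimated correlation, fry and cameraPR were alternatives. The naming rule took genes passing the edgeR threshold, up to 4 members with the smallest p of each list and 16 fixed genes. No gene passed the threshold, so its first part was empty, and it was applied to the DESeq2 calls after the values were seen, which gave 10 rises and 10 falls. Library properties and list means were compared with exact two-sided sign-flip tests over all 65536 sign patterns of 16 pairs. Correlations used 100000 permutations.

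The models were tested on simulated data, drawn for 14364 genes from the real means, library sizes and dispersions with 200 genes changed. For the limb comparison, edgeR recovered 24.0% of genes changed 1.5-fold and 71.0% of those changed 2-fold with 5 false calls, DESeq2 43.0% and 82.0% with 29 false calls, and limma-voom 27.0% and 73.0% with 9. Labels were swapped within participants in 100 ways for edgeR and the lists (50 for DESeq2), and prefix labels were reassigned in 50 ways, the real labels included. Alternatives covered normalization, filters, tools, the block, thresholds, code prefix, titles ending in a suffix, composition covariates and the removal of each participant. The removal of participants 11 and 12 together, the first principal component as a covariate, voom quality weights, sign-flip tests of lists and DESeq2 on fewer participants were added after seeing the data. Genes on the Y chromosome, XIST and TSIX stayed in the models and are not reported. P-values of the gene tests with the block and of the sign-flip tests rest on the spread of limb differences between these participants. Camera compares the members of a list with all other genes tested. Its p at the preset correlation does not take in how strongly the members of that list varied together between these biopsies.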

Results

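Gene expression was measured by RNA sequencing in quadriceps muscle biopsies from people with a torn anterior cruciate ligament (ACL), a ligament that stabilises the knee, taken before reconstruction surgery. There were 32 libraries, 16 from injured and 16 from non-injured limbs, and each code in the sample titles appeared once in each limb, which gave 16 pairs, numbered here as participants 1 to 16. The total estimated count per library ran from 14845423 to 22050821, with a median of 17661893. After filtering, 14364 genes were tested. The series title places the comparison in the context of protein synthesis, anabolic signalling and quadriceps wasting after ACL tear, so genes of these processes were examined whatever their result.

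The first comparison asked which genes differed between the injured and the non-injured limb of a participant. In the injured limb, mean values were higher for the acetylcholine receptor subunit CHRNA1, the neurotrophic factor GDNF, the transcription factor RUNX1, the phosphodiesterase PDE11A and the histone deacetylase HDAC4, and lower for the haemoglobin genes HBA1 and HBA2, the monocarboxylate transporter SLC16A3 and the orphan nuclear receptors NR4A1 and NR4A3. None of these passed edgeR's quasi-likelihood test after adjustment over all genes. edgeR called 0 genes at a Benjamini-Hochberg adjusted p under 0.05, with a smallest adjusted p of 0.27, and 999 genes had an unadjusted p under 0.05 (405 higher and 594 lower). The number of genes tested gives 718 at that level for evenly spread p, while labels swapped within participants gave a median of 209 and up to 3989. DESeq2 with the same block called 77 genes, 26 higher and 51 lower, all 77 of which had an unadjusted p under 0.05 in edgeR, and limma-voom called 0. The DESeq2 calls below passed in neither of the other tools with the same block, although voom with quality weights called GDNF and edgeR within prefix M called IL18. They were described after the calls of the tools had been seen.

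Among the DESeq2 calls, CHRNA1 (chromosome 2, 175612320 to 175629200, minus strand, hg19) averaged 11.2 ± 5.48 CPM in non-injured and 40.5 ± 27.4 CPM in injured limbs (SD, n = 16 each). Its edgeR log2 fold change was 1.58 (SE 0.35), it was higher in 13 of 16 participants, and its adjusted p was 0.0011 by DESeq2 and 0.27 by edgeR. GDNF (chromosome 5, 37812779 to 37839788, minus strand) went from 4.37 ± 3.05 to 13.8 ± 12.4 CPM, a log2 fold change of 1.36 (SE 0.29), and was higher in 15 of 16 participants. RUNX1 (chromosome 21, 36160098 to 37376965, minus strand) had a log2 fold change of 1.36 (SE 0.32) and HDAC4 (chromosome 2, 239969864 to 240323348, minus strand) of 0.95 (SE 0.23). Each was higher in 13 of 16 participants. Among DESeq2 calls with a mean of at least 1 log2 CPM, the same direction in at least 12 participants and no clone name, the remaining largest rises were PDE11A, the calcium sensor HPCAL4, the cytokine IL18, the mTORC1 regulator SESN3, TTC39B and the small GTPase RHOB, with edgeR log2 fold changes from 0.81 for RHOB to 1.14 for PDE11A.

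On the side of lower expression, SLC16A3 (chromosome 17, 80186273 to 80219005, plus strand), which carries lactate across the cell membrane, went from 238 ± 132 to 117 ± 109 CPM (SD, n = 16 each), a log2 fold change of -1.25 (SE 0.29), and was lower in 13 of 16 participants, with a DESeq2 adjusted p of 0.003. NR4A3 and NR4A1, which respond to exercise, had log2 fold changes of -1.43 (SE 0.34) and -0.90 (SE 0.21) and were lower in 14 and 13 participants. NR4A3 was weakly expressed, at 3.95 ± 4.46 CPM in non-injured and 1.56 ± 2.38 CPM in injured limbs, with a mean of 0.573 log2 CPM. The conditions used for the rises were not met by NR4A3, nor by HBB and FCGR3B (below). Under those conditions, the largest falls besides SLC16A3 were HBA2, HBA1, NOV, FAM57B, CTXN3, SNAI3, CHRDL2, SCN4B and RASL12. Their edgeR log2 fold changes ran from -0.93 for RASL12 to -2.96 for HBA2. HBA1 and HBA2 are near-identical copies, so how the authors' counting shared reads between them leaves each value uncertain.

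The gene lists asked whether groups of genes moved together against all other genes tested. Genes of the denervation and neuromuscular junction list were higher in the injured limb, and 5 of its 27 measured members rose when adjusted over the list alone (GDNF, CHRNA1, RUNX1, HDAC4 and the receptor subunit CHRND), 0 fell, and 0 passed over all genes in edgeR, whereas 4 rose in DESeq2. CHRND, named after its value was seen like MYH3 and COLQ below, had a log2 fold change of 0.90 (SE 0.29). Other members were not called: MYOG had 0.53 (SE 0.21), NCAM1 -0.07 (SE 0.24), the embryonic myosin MYH3 -0.20 (SE 0.29) and COLQ -0.43 (SE 0.17). The list passed camera with the preset correlation (adjusted p = 8.76e-07), and it was the only one of 30 pathway lists that also passed with an estimated correlation (adjusted p = 0.0416). The list mean was higher in 12 of 16 participants by 0.334 ± 0.393 log2 units (SD), with an exact two-sided sign-flip p of 0.00488, or 0.0732 adjusted over the 30 lists. The call with an estimated correlation was lost when any of 10 of the 16 participants was left out, while the list mean stayed between 0.288 and 0.383. Without participant 12 the adjusted p was 0.282 and the list mean 0.345 ± 0.404 log2 units (SD, n = 15). The list mean did not fall there, while the estimated correlation between members rose from 0.0549 to 0.0756. The adjusted p at the preset correlation also weakened, from 8.76e-07 to 6.45e-05, so the higher correlation alone does not account for the change. Camera compares the list with all other genes, and the median log2 fold change of all genes moved from -0.036 to -0.0003 without participant 12.

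**Figure D1:**
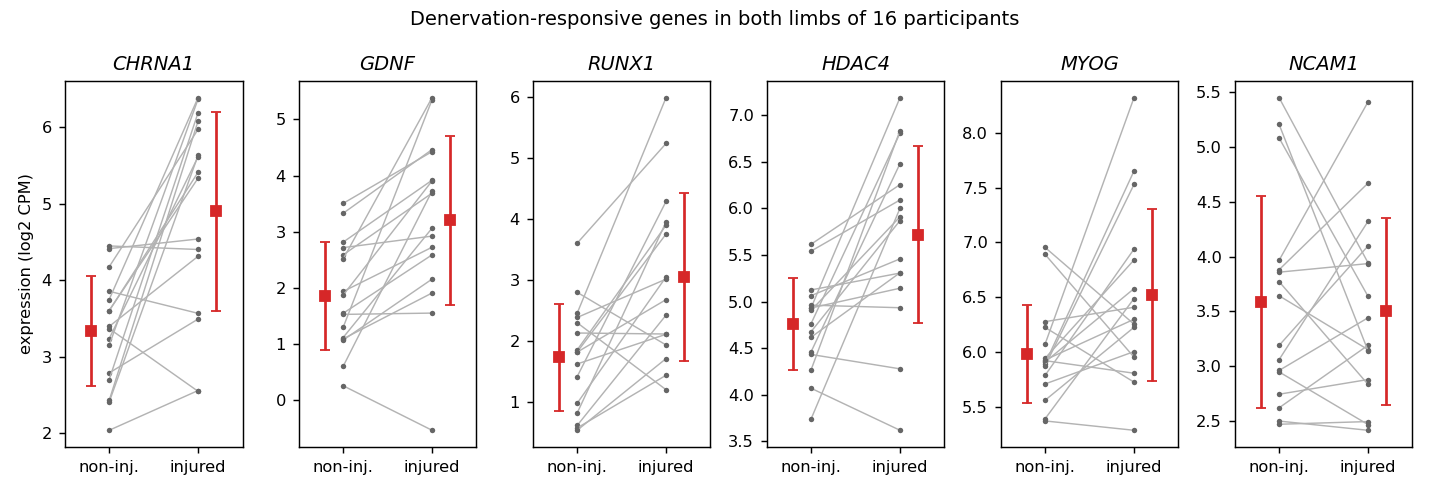
Expression of 6 genes of the denervation list in log2 CPM in the non-injured (non-inj.) and injured limb. Grey points joined by a line are the limbs of 1 of 16 participants, red squares and bars are the mean ± SD, and each panel has its own vertical axis; CHRNA1 was higher in the injured limb in 13 participants and GDNF in 15.

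Transcripts of energy metabolism were lower in the injured limb under the preset correlation of camera. All 79 nuclear-encoded oxidative phosphorylation genes had a log2 fold change below 0 (median -0.25; adjusted p = 1.12e-07, and 0.792 with an estimated correlation), none of them called on its own, with CYC1 at -0.36 (SE 0.13) and COX5A at -0.39 (SE 0.17). All 13 mtDNA-encoded genes were below 0 as well (median -0.47; adjusted p = 1.57e-05, and 0.686 with an estimated correlation), among them MT-CO2 and MT-ND1. The mtDNA-encoded list mean was lower in 11 and higher in 5 participants, at -0.439 ± 0.861 log2 units, or -0.274 ± 0.574 (SD, n = 15) without participant 12. Of 29 glycolysis and glycogen genes 26 were below 0 (median -0.21; adjusted p = 1.57e-05, and 0.686 with an estimated correlation), with PKM at -0.55 (SE 0.19) and LDHA at -0.65 (SE 0.22). The glycolysis list mean was lower in 13 of 16 participants, with an exact sign-flip p of 0.0025 that became 0.0732 when adjusted. The TCA cycle (17 of 19 below 0) and fatty acid oxidation (23 of 29) lists had preset adjusted p of 0.00362 and 0.0448, and adjusted p of 0.686 and 0.792 with an estimated correlation. The preset call for fatty acid oxidation was lost without any 1 of participants 1, 2, 3, 4, 6, 9, 10, 13, 14 and 15 (adjusted p up to 0.358). Members of these lists varied together, with an estimated correlation between genes of 0.692 for oxidative phosphorylation. Participants also varied: the oxidative phosphorylation mean was lower in 10 and higher in 6 of the 16 (-0.254 ± 0.725 log2 units, sign-flip p = 0.18).

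Genes of protein synthesis and breakdown, which the series title concerns, gave few differences. The atrophy-associated list (adjusted p = 0.309), the myostatin, activin and TGF-beta list (0.333), the insulin, IGF and mTORC1 list (0.368), proteasome subunits (0.716), autophagy and lysosome genes (0.801) and translation factors (0.955) did not pass. The ubiquitin ligases FBXO32 and TRIM63, whose transcripts mark muscle wasting in many settings, had log2 fold changes of 0.00 (SE 0.15) and -0.16 (SE 0.17). MSTN, which limits muscle growth, was at 0.17 (SE 0.29), IGF1 at -0.17 (SE 0.20) and the S6 kinase RPS6KB1 at -0.19 (SE 0.30), and none was called by edgeR or DESeq2. SESN3 rose when adjusted over its list alone, at 0.92 (SE 0.20) and higher in 14 of 16 participants. EIF4EBP1, a repressor of cap-dependent translation, was at -0.58 (SE 0.24, unadjusted p = 0.024, adjusted p = 0.65). Cytosolic ribosomal proteins were below 0 in 76 of 79 members (adjusted p = 0.00362, and 0.92 with an estimated correlation), but their list mean was lower in 7 and higher in 9 of the 16 participants (-0.178 ± 0.900 log2 units, SD, sign-flip p = 0.435). That call was lost without any 1 of participants 1, 3, 4, 10, 14 and 15 (adjusted p up to 0.59), and with 1 participant left out the list mean ran from -0.279 to -0.0841. Ribosome biogenesis genes were above 0 in 25 of 39 (adjusted p = 0.0293, and 0.686 with an estimated correlation), with MYC at 0.62 (SE 0.27). The biogenesis call was lost without any 1 of participants 6, 7, 8, 9, 10 and 13 (adjusted p up to 0.124), and its list mean of 0.0312 ± 0.236 ran from 0.00948 without participant 13 to 0.0715 without participant 12.

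Fast-fibre genes were below 0 in 16 of 18 members (adjusted p = 0.000794, and 0.686 with an estimated correlation), of which the kinase gene MYLK2 fell over the list alone at -0.68 (SE 0.20), and MYH2 and MYH1 were at -0.28 (SE 0.21) and -0.33 (SE 0.31). Slow-fibre genes were below 0 in 15 of 17 (adjusted p = 0.0448, and 0.885 with an estimated correlation), with MYH7 at -0.35 (SE 0.27). The slow-fibre call was lost without any 1 of participants 1, 2, 3, 4, 6, 9, 10, 15 and 16 (adjusted p up to 0.339). Collagens and extracellular matrix genes were below 0 in 51 of 55 (adjusted p = 0.000185, and 0.792 with an estimated correlation), with COL1A1 at -0.32 (SE 0.21) and COL3A1 at -0.42 (SE 0.21). Their list mean was -0.249 ± 0.629 log2 units, or -0.138 ± 0.460 (SD, n = 15) without participant 12. Myogenic regulation and satellite cell genes (14 of 19 above 0, PAX7 at 0.15, SE 0.14) and immediate early genes (12 of 17 above 0, EGR1 at 0.90, SE 0.36) had adjusted p of 0.0218 and 0.0223, and 0.686 for both with an estimated correlation. The myogenic call was lost without any 1 of participants 1, 3, 5, 6, 9, 10 and 11 (adjusted p up to 0.172), and its list mean rose from 0.0944 to 0.158 without participant 12. The immediate early call was lost without participant 10 or 14 (adjusted p up to 0.0974), and its list mean of 0.0752 ± 0.617 ran from 0.0166 without participant 10 to 0.186 without participant 12. The mitochondrial biogenesis and exercise-responsive list did not pass (adjusted p = 0.474), with PPARGC1A at -0.23 (SE 0.19), but its members NR4A1 and NR4A3 fell over the list alone. The remaining lists were not called: circadian clock (0.183, with TEF alone rising over the list), oxidative stress (0.257), sarcomere and costamere (0.44), calcium handling and inflammatory cytokines (0.474 each), complement (0.742), heat shock and ATF4 targets (0.745 each), interferon-stimulated genes (0.801) and cell cycle (0.955).

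**Figure D2:**
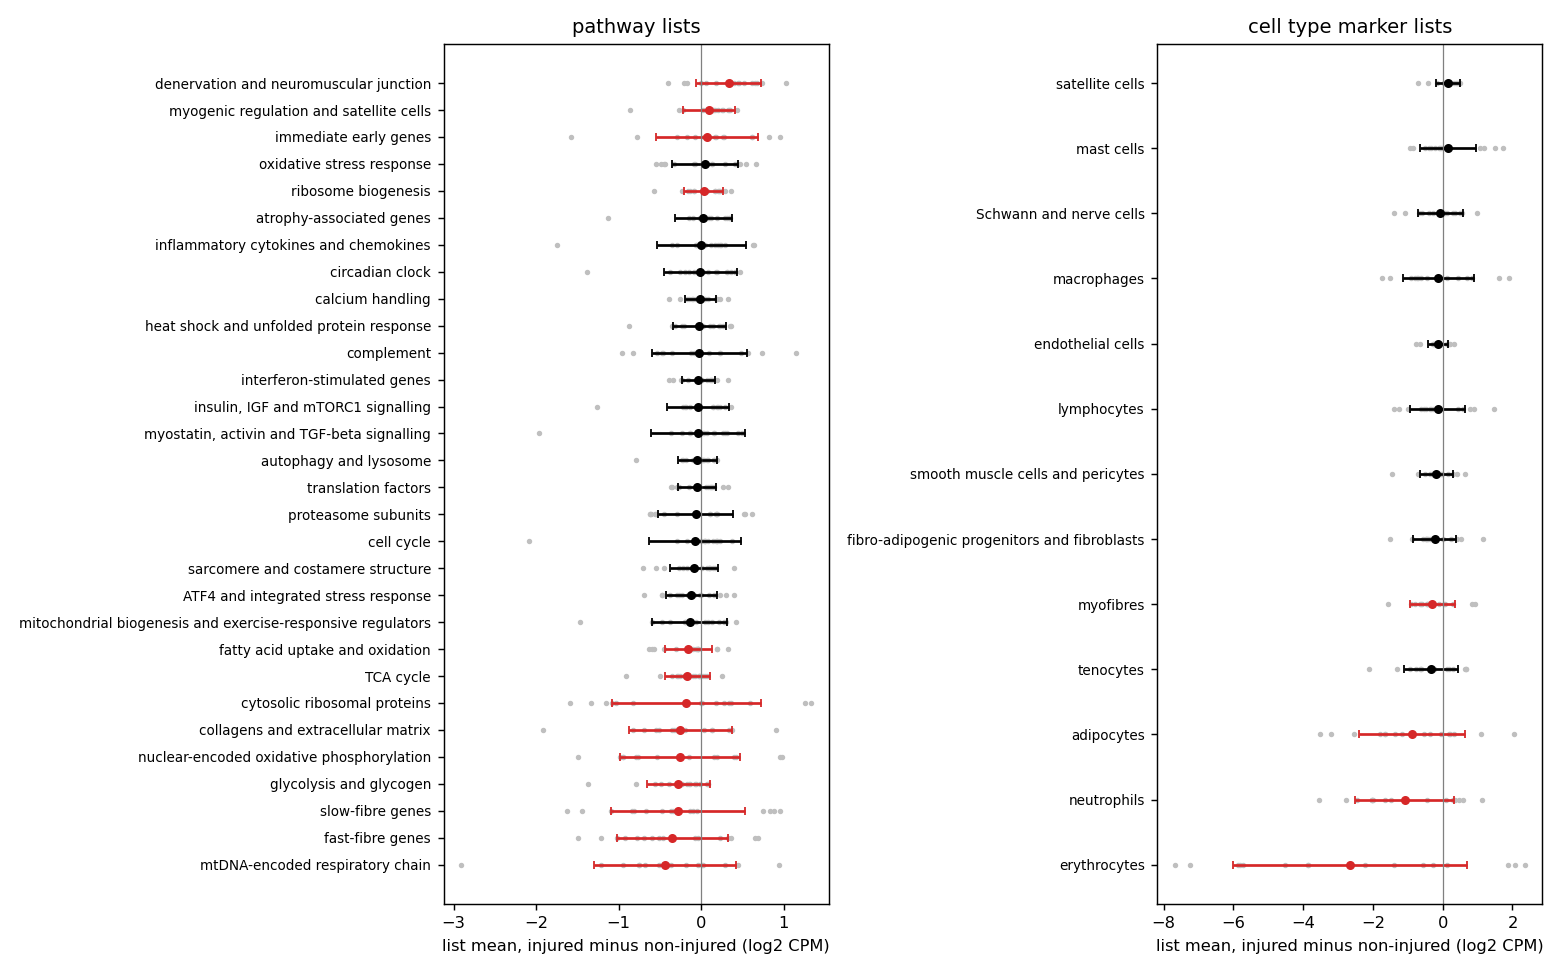
Difference of each list mean between limbs (injured minus non-injured, log2 CPM) for 30 pathway lists and 13 cell type marker lists. Grey points are the 16 participants, larger points and bars are the mean ± SD, and red marks lists with a camera adjusted p under 0.05 at the preset correlation, of which the denervation list alone passed with an estimated correlation.

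Marker lists of the cell types that a muscle biopsy can hold were tested in the same way. The 3 measured erythrocyte genes, HBA1, HBA2 and HBB, were lower in the injured limb, with log2 fold changes of -2.77, -2.96 and -2.52 (SE 0.95, 0.98 and 0.98). All 3 fell over the list alone (adjusted p = 0.000146 by camera, and 0.18 with an estimated correlation). Of the 5 neutrophil genes, all below 0, FCGR3B fell over the list alone (log2 fold change -2.01, SE 0.63). It was weakly expressed, at 1.43 ± 1.01 CPM in non-injured and 0.807 ± 1.35 CPM in injured limbs (SD, n = 16 each). Its value was lower in 11 of 16 participants. The neutrophil list had an adjusted p of 0.000208 by camera, and 0.18 with an estimated correlation, and its mean was lower in 10 and higher in 6 participants. The 10 adipocyte genes were all below 0 (adjusted p = 8.27e-05, and 0.225 with an estimated correlation), with FABP4 at -0.78 and CIDEC at -1.63, and 13 of 14 myofibre genes were below 0 (adjusted p = 0.00102, and 0.37 with an estimated correlation). Satellite cells (0.117), fibro-adipogenic progenitors (0.15), tenocytes (0.153, with FMOD falling over the list alone), mast cells (0.154), smooth muscle and pericytes (0.332), endothelial cells (0.411), lymphocytes (0.89), macrophages (0.955) and Schwann and nerve cells (0.967) did not pass.

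Properties of the libraries did not differ detectably between limbs by exact sign-flip tests adjusted over 5 properties. The mtDNA-encoded share of counts was 12.2 ± 3.45% in non-injured and 10.9 ± 4.56% in injured limbs (SD, n = 16 each, adjusted p = 0.864). The haemoglobin share was 0.197 ± 0.222% and 0.146 ± 0.324%, with medians of 0.117% and 0.0188%, and was lower in the injured limb in 12 participants (adjusted p = 0.864). On the log2 scale the erythrocyte list mean differed by -2.66 ± 3.36 (SD), with a sign-flip p of 0.00787, or 0.0621 adjusted over the cell type lists. The adjusted p was 0.975 for both the total count and the number of genes with at least 10 counts, and 0.864 for the share of the 10 largest genes. The injured-limb library of participant 12 stood apart, with 0.747% of counts in mtDNA-encoded genes and 11065 genes with at least 10 counts, and that of participant 11 had 3.73% of counts in mtDNA-encoded genes.

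Sample codes began with A (4 participants) or M (12 participants), a difference the labels do not explain. edgeR found 0 genes whose limb difference depended on the prefix, with 866 genes at an unadjusted p under 0.05, and limma-voom found 0, with 954. With 4 participants against 12, a dependence on the prefix could be missed. The smallest p of the reported genes was that of IL18, whose log2 limb difference was lower under A than M (-2.17, SE 0.43, edgeR adjusted p = 0.655). Within prefix A, edgeR called 1 gene, RP4-545K15.3, and within prefix M 1 gene, IL18, both named after their values were seen.

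Across the 16 participants, the limb difference of the oxidative phosphorylation list mean rose with that of cytosolic ribosomal proteins, with Pearson r = 0.93 and Spearman rho = 0.93. Each had a permutation p of 1e-05, the smallest that 100000 permutations can give, and of 4e-05 adjusted over 4 relations. Both differences also moved with the limb difference of the log2 TMM factor, a measure of library composition examined after the relation was seen (r = -0.742 and -0.852, permutation p = 0.00103 and 6e-05). With that difference taken out, r between the lists was 0.841. Their r with the difference in the first principal component was 0.364 and 0.656, or 0.873 and 0.937 without participant 12. Between the lists, Pearson r was 0.88 without the 2 participants farthest from the median on the x axis and 0.91 within prefix M, while prefix A held only 4 participants. Collagens (r = -0.03, rho = -0.29), macrophages (r = 0.34, rho = 0.29) and the denervation list (r = -0.31, rho = -0.27) did not vary detectably with oxidative phosphorylation, with permutation p of 0.909, 0.194 and 0.239 for r, or 0.909, 0.319 and 0.319 adjusted, and of 0.279, 0.283 and 0.315 for rho, all 0.315 adjusted.

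**Figure D3:**
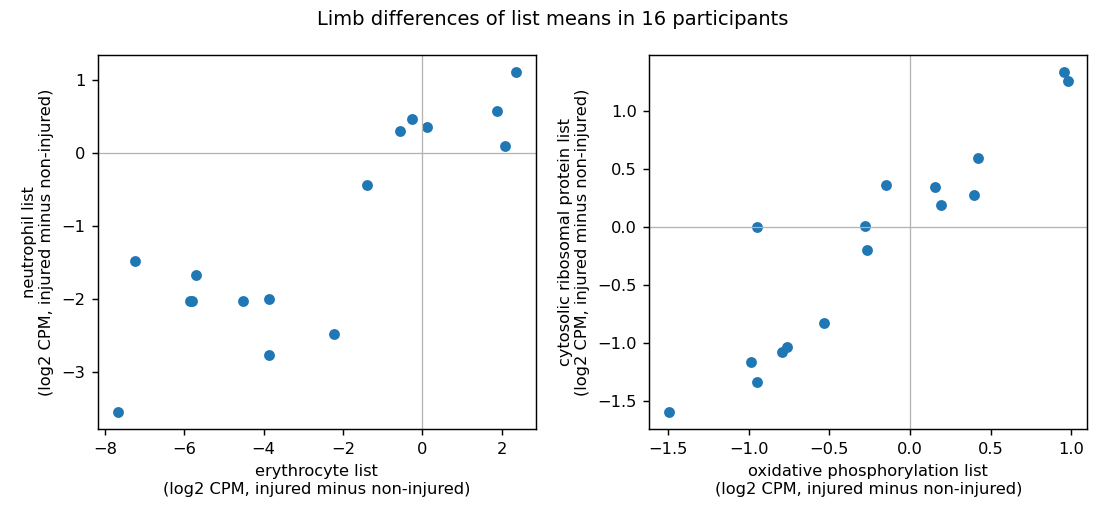
Limb differences of list means (injured minus non-injured, log2 CPM) in 16 participants, 1 point each. Left, erythrocyte against neutrophil markers; right, oxidative phosphorylation against cytosolic ribosomal proteins, where r was 0.93.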

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

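DESeq2 called 77 genes with all participants, 58 without participant 12 (51 shared) and 43 without participants 11 and 12 (36 shared), against 0 by edgeR; voom with quality weights called 1, GDNF, and 0 without participant 12, and edgeR called 1 gene within prefix A and 1 within prefix M. The settings without participants 11 or 12 other than the planned removal of each, the principal component, quality weights and list sign-flip tests were chosen after seeing the data. edgeR called 0 under RLE, upper quartile or library-size scaling (which moved the median log2 fold change of all genes from -0.04 to 0.08), both other filters, both mtDNA settings, no replicate block (0, with 702 at an unadjusted p under 0.05) and without each participant; both stricter thresholds could give only 0. Genes at an unadjusted p under 0.05 numbered 2544 within prefix A, 1864 with the first principal component, 1759 with quality weights and 1750 with weights without participant 12, and 728 to 1305 without each participant. The 13 pathway lists became 1 with an estimated correlation (0 without participant 12, and 0 without 11 and 12), 0 by fry, 0 by sign-flip tests, 5 without titles ending in the suffix, and 7 to 14 without each participant (7 without participant 10). The 4 cell type lists became 0 with an estimated correlation (0 without participant 12, and 0 without 11 and 12) and 2 by fry (erythrocytes and neutrophils). They became 0 by sign-flip tests and numbered 4 to 5 without each participant. Without the block 10 pathway and 4 cell type lists passed. Directions turned within prefix A for translation factors (adjusted p = 0.00197), oxidative stress (0.00211), heat shock (0.00575), ribosome biogenesis (0.0951), immediate early (0.997) and mtDNA-encoded genes (0.997), within prefix M for ribosomal proteins (0.167) and the proteasome (0.0239), and without the suffixed titles for ribosomal proteins (0.714) and slow-fibre genes (0.926); the cause was not tested. Among 185 genes the naming rule covers, values of uncalled genes changed sign 67 times, in 48 genes, over the other settings, and 14 times when 1 participant was left out; these were not counted as reversals. Library properties, the prefix comparison, the 4 relations and the pairing check kept their side of the threshold. At these depths, simulated changes of 1.5-fold were mostly missed by edgeR (24.0% recovered).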

Other observations

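The tests of nerve tissue, of transcript length and GC content, of the muscle fibre share and of label swaps for the denervation list were chosen after related results had been seen. ABCG1, a cholesterol exporter, was the gene higher in the injured limb of 16 of 16 participants among the DESeq2 calls examined here, at a log2 fold change of 0.46 (SE 0.11; edgeR adjusted p = 0.32, DESeq2 adjusted p = 0.011). MASP1, a complement-activating protease, had the smallest edgeR p, with a log2 fold change of -0.82 (SE 0.15), lower in 14 of 16 participants (edgeR adjusted p = 0.27, DESeq2 adjusted p = 0.00106). Both were named after their values were seen.

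Label swaps within participants bear on whether chance can be excluded. The 0 genes of edgeR cannot be tested this way, since all 100 splits give at least 0 (highest other 2). For the 999 genes at an unadjusted p under 0.05, 11 of 100 splits gave as many (median 209, highest other 3989), so chance is not excluded. What the split with 3989 set apart was not examined. For the 77 DESeq2 calls 1 of 50 splits, the real one, gave as many (highest other 22), the smallest share that 50 splits can give. Label swaps thus seldom gave so many calls, but chance is not excluded. DESeq2 made 29 false calls in simulated data, but those data held 200 changed genes, so that count cannot be set against the 77. With the same block, edgeR and limma-voom called 0 genes. For the 13 pathway lists 3 of 100 splits gave as many (highest other 14, median 6), and for the 4 cell type lists 27 of 100 did (highest other 9). For the prefix comparison, all 50 splits gave at least 0 genes, and the highest other was 3833, a split that was not examined further either.

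Genes of the denervation list were higher in the injured limb by a mean of 0.334 log2 units, and by 0.345 without participant 12, where the call with an estimated correlation was lost (adjusted p = 0.0416 before and 0.282 after). With the first principal component as a covariate the mean log2 fold change was 0.34 against 0.36 without it. The fry p was 0.0057, not adjusted for the choice of this list among 30. That component mainly set apart the injured-limb library of participant 12 (score 292, next highest 119). The difference was thus not explained by this component, but whether another gradient of RNA quality or composition contributed cannot be decided from it. Schwann and nerve markers had a mean difference of -0.0701 log2 units, with an upper 95% limit of 0.27. The denervation list exceeded them by a mean of 0.405 over 16 participants, with an exact sign-flip p of 0.0192. It was picked for its rise, however, and both lists hold NCAM1. These values argue against an equal rise of both lists, while a smaller increase of nerve tissue in the injured-limb biopsies stays open. Chance is not excluded, since the sign-flip p adjusted over 30 lists was 0.0732. In 65 of 100 splits some pathway list had a preset camera p as small as the real 5.84e-08 (smallest other 9.19e-34). That count decides little, because the smallest p can come from lists whose members varied together far more. One such list is oxidative phosphorylation (estimated correlation 0.692, against 0.0549 here), for which the preset correlation of 0.01 makes p too small. The denervation list alone was as extreme in 2 of 100 splits, and any list passed with an estimated correlation in 3 of 100. A difference in muscle fibres between the injured and the non-injured limb stays open, untested.

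Haemoglobin and neutrophil transcripts were lower in the injured limb with camera's preset correlation. The call was lost for both lists with an estimated correlation (adjusted p = 0.18 each) and by sign-flip tests (adjusted p = 0.0621 each). Only just, fry kept it for both (adjusted p = 0.0469 each). Less blood in the injured-limb biopsies is a candidate explanation: the differences of both lists rose together over 16 participants, with Pearson r = 0.857 (permutation p = 8e-05) and Spearman rho = 0.768 (permutation p = 0.00083), and r was 0.82 without the 2 participants farthest from the median and 0.813 within prefix M (12 participants). The mean log2 fold change of the haemoglobin genes was -2.81 with the first principal component and -2.75 without it. That component did not explain the haemoglobin difference. Since it mainly set apart the injured-limb library of participant 12, whether another gradient between libraries contributed cannot be decided from it. The neutrophil differences lay in a lower and an upper group with a gap between them, so the relation may rest in part on that gap, and whether the limbs differed in blood content or the biopsies in handling was not tested.

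Oxidative phosphorylation transcripts were lower in the injured limb with camera's preset correlation, a call lost with an estimated correlation (adjusted p = 0.792) and not seen by a sign-flip test (p = 0.18, with the list higher in 6 of 16 participants). Transcript length and GC content cannot be told apart from it. The list was compared with genes matched on transcript length, GC content and expression. It exceeded these matched genes in its fall (-0.254 against -0.179) by -0.0751 ± 0.225 (SD, n = 16 participants), with an exact sign-flip p of 0.201. Since expression was part of the match, the fall of the matched genes cannot be credited to length and GC content alone. A bound set before the result, the central 95% of 10000 random lists of matched genes (-0.204 to -0.111), did not hold the list median of -0.251, which lay below all of them (lowest -0.234), but that range was too narrow, since random lists were drawn gene by gene and these members had an estimated correlation of 0.692. A gradient between libraries (mean log2 fold change -0.29 with the first principal component and -0.25 without it, fry p of 0.11 and 0.16) and a lower share of muscle fibre RNA (mean difference to the sarcomere list -0.165, exact sign-flip p of 0.342) cannot be told apart either. The myofibre marker list had a mean difference of -0.298 ± 0.637 log2 units (SD, n = 16), against -0.254 for oxidative phosphorylation, so the sarcomere list alone does not describe the fibre share. The spread between participants keeps all 3 explanations open, and a lower mitochondrial content of the injured limb is untested.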
